A study of Rattus norvegicus with 6 samples.

How the data were processed

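RNA from 6 samples of rat INS-1 cells was measured on 1-colour Agilent arrays, 3 labelled as geniposide-treated (10 µmol/L for 24 h) and 3 labelled as untreated. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was purified on columns, its integrity was checked on a Bioanalyzer, and it was amplified and labelled with Cy3.

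The deposited scanner files hold spot intensity values. Per the file headers, Agilent Feature Extraction 12.0.3.1 made them, while the submitters' processing notes name version 10.7 of the same program. The processed intensity had a background surface subtracted and a spatial trend removed within each array, per the file headers, with no scaling between arrays. The authors also deposited a table of log2 values with 45807 rows, 1 per probe or control name. The submitters' processing notes name limma without saying what it was used for. Each column of that table correlated with the log2 processed intensity of its own array (lowest r = 0.999). The column medians lay at 5.42 for geniposide 1, 5.42 for geniposide 2, 5.42 for geniposide 3, 5.41 for untreated 1, 5.42 for untreated 2 and 5.41 for untreated 3. The median difference between the table and quantile-normalized log2 signal was 0.0088, so the table runs in the same direction as the signal and on the log2 scale. Its exact normalization steps are not given in the sources used here.

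Each array held 62976 spots, of which 1319 were controls. The other 61657 spots belonged to 45751 probes of 60 bases, 29845 with 1 spot and 15906 with 2 spots. The probes carry running numbers in place of gene symbols or accessions (0 probes had a gene symbol), the files list their positions as unmapped, and 0 probe numbers matched the RefSeq gene table used for names. Gene names, genome positions and the split into messenger and long noncoding RNA were therefore not analysed here. The gene lists fixed before the data were examined could not be applied for the same reason.

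The log2 processed intensity of each array had the array's 75th percentile subtracted. Spots of 1 probe were averaged after control spots and spots marked as non-uniform or population outliers were left out. The scanner software marked 49, 2 and 3 probe spots in this way on geniposide arrays 1, 2 and 3, and 6, 5 and 5 on untreated arrays 1, 2 and 3. Probes without an unmarked spot on some array, 33 in number, were left out, so 45718 were analysed. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which kept 29246 probes, or 64.0%. No spot was saturated (0 on each array). More than 50% of probes were well above background on each array, so the percentile was taken over all analysed probes.

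Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, group as the sole term), with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05 on the adjusted p. Differences are geniposide minus untreated on the log2 scale. For a probe that was not well above background on any array of a group, the fold is a bound. It sets the mean of the brighter group against the dimmer group's mean of, per array, the lowest signal among probes well above background or the probe's own signal, whichever was higher. The number of arrays limits the precision of every value.

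The rule for the probes to be described was set before the data were examined. It asked for genes past the threshold whose arrays did not overlap between groups, the largest changes first, and 10 fixed beta-cell genes in any case. Where fewer than 6 passed in a direction, the places were to be filled by the smallest p and given as values that did not pass. No probe passed and no probe is paired with a gene, so the 6 probes with the smallest p in each direction were taken. Since the files do not pair probe numbers with genes, 2 numbers per direction are printed from these, with the sequence of the probe.

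The fit was tested on simulated data built from the means and spreads of the 29246 probes, with 200 changed probes in each of 5 runs of the geniposide against untreated comparison. It recovered 60.0% of the planted 1.5-fold changes, 81.8% of the 2-fold changes and 97.3% of the 4-fold changes, and called 0.022% of the unchanged probes. The simulated noise was independent between probes and had the same spread in both groups. It left out the wider spread of the geniposide arrays and deviations shared by many probes of 1 array. These shares are therefore not the power of the real comparison.

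Alternatives covered background correction by normexp with an offset of 50, quantile and median scaling, a percentile over probes well above background on all 6 arrays, the authors' deposited table, no filter and a stricter filter, the variance model, array weights, the slide row as a fixed and as a random block, the replicate number as a block, other thresholds, and each array left out in turn. All arrays lay on 1 slide with 1 scan date, so the position on the slide was the remaining batch that the files name. Geniposide 1 shared row 1 with the 3 untreated arrays, and geniposide 2 and 3 lay in row 2. Untreated 1, 2 and 3 lay in columns 1, 2 and 3 of the slide, geniposide 2 in column 2, and geniposide 1 and 3 in column 4, which held no untreated array. The column is therefore also partly confounded with the treatment, and no alternative for it was run.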

Results

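INS-1 is a rat insulinoma line that secretes insulin and is widely used as a model of the pancreatic beta cell. Geniposide is an iridoid glucoside from gardenia fruit, which the labels describe as an agonist of the GLP-1 receptor. Through this receptor the incretin hormone GLP-1 raises insulin secretion. The arrays addressed which messenger and long noncoding RNAs differ between cells kept with 10 µmol/L geniposide for 24 h and untreated cells. There were 3 arrays per group.

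Probes well above background made up 67.0%, 64.0% and 61.3% of all probes on geniposide arrays 1, 2 and 3, against 67.4%, 66.5% and 65.1% on untreated arrays 1, 2 and 3. The group means were 64.1% ± 2.82 (SD, n = 3) and 66.3% ± 1.16 (SD, n = 3), which did not separate (exact two-sided permutation test, p = 0.3, where the smallest p that 3 against 3 can give is 0.1). The 75th percentile of the processed intensity was 385 ± 51.8 (SD, n = 3) in the geniposide group and 383 ± 36.6 (SD, n = 3) in the untreated group. The 7 spike-in probes well above background on every spot measure RNA added in known amount. Their mean lay 3.04 ± 0.267 (SD, n = 3) log2 units above that percentile in geniposide arrays. In untreated arrays it lay 2.91 ± 0.124 (SD, n = 3) above it (exact two-sided permutation test, p = 0.7). Single probes ran from -1.90 to 8.03 in the geniposide group, so not all of them were bright.

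The 6 arrays resembled one another closely across the 29246 tested probes. Pearson's r, across probes within pairs of arrays, was 0.998 for each pair of untreated arrays, and ranged from 0.995 to 0.997 between geniposide arrays and from 0.994 to 0.997 between arrays of different groups. The first principal component held 39.9% of the variance and set geniposide 3, at -34.2, apart from all other arrays. Geniposide 1 and 2 lay at -1.29 and -4.99 on it, and untreated 1, 2 and 3 at 11.7, 11.8 and 16.9. The second component, with 20.2% of the variance, placed geniposide 1 and 2 at 19.6 and 14.3 and geniposide 3 at -11.6, beyond the untreated arrays at -6.96, -7.64 and -7.63. The median SD of a probe within a group was 0.103 log2 units for geniposide and 0.0687 for untreated cells, and 67.0% of probes had the larger variance in the geniposide group. Geniposide 1 and 2 taken alone had a median SD of 0.0611, against 0.0561 for pairs of untreated arrays. Over 9392 probes with 2 spots, the difference between 2 arrays of a group repeated between the separate spots. Spearman's rho, across probes, was 0.203 to 0.286 for pairs of untreated arrays and 0.249 for geniposide 1 with 2. It was 0.583 and 0.534 for geniposide 3 with geniposide 1 and 2. Differences between arrays of different groups repeated too, with 0.344 to 0.437 for geniposide 1 or 2 and 0.557 to 0.622 for geniposide 3.

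**Figure D1:**
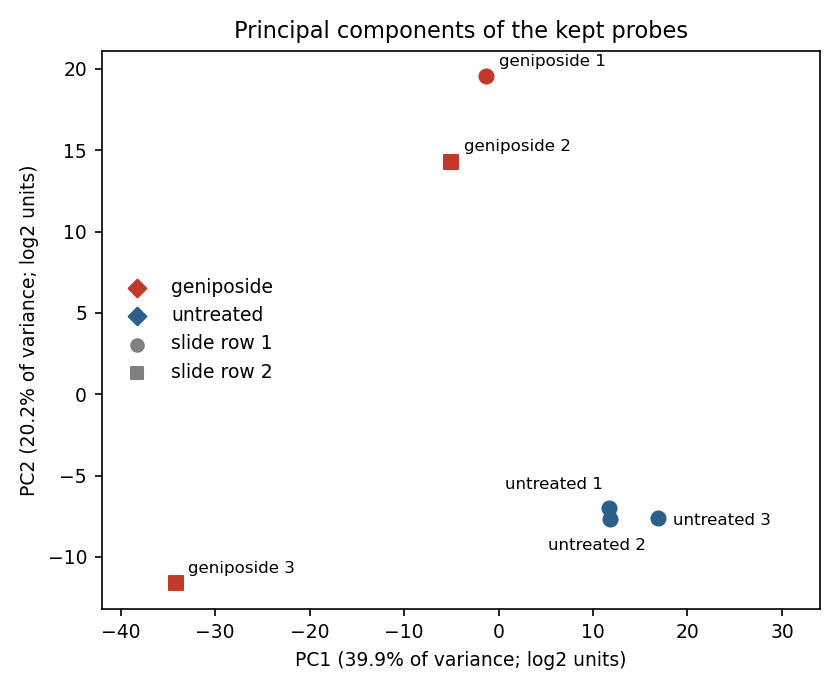
Scores of the 6 arrays on the first principal component (horizontal axis, 39.9% of variance) and the second (vertical axis, 20.2%), in log2 units. Red marks are geniposide arrays and blue marks untreated arrays, with circles for row 1 and squares for row 2 of the slide. Geniposide 3 lies at -34.2 on the first component, far from the other 5 arrays.

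The comparison of geniposide-treated with untreated cells found 0 probes past the threshold with limma, 0 higher and 0 lower, and the smallest adjusted p was 0.0878. At an unadjusted p under 0.05 there were 3619 probes, 12.4% of those tested, where 1462 would be due by chance. That count depended on the processing and on single arrays, with 2158 after normexp background correction, 1129, below the chance number, with scaling on the spike-in probes, and 2979, 2632 and 2370 without untreated 1, 2 and 3. It was 3789, 3615 and 3620 without geniposide 1, 2 and 3, 4862 with array weights and, over all 45718 probes, 4371 with no filter. Of the 3619, 2143 were higher and 1476 lower in geniposide-treated cells. The arrays of the groups did not overlap at 6210 probes, or 21.2%, where chance gives 10%. Differences were small. The median 95% interval reached 0.18 log2 units, or 1.14-fold, to either side of the estimate. For 28559 probes, 97.7%, the 95% interval excluded a 2-fold difference in either direction, and 55 probes differed by 2-fold or more as measured. Of those 55, 44 also had an unadjusted p under 0.05, 33 of them higher and 11 lower.

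The count past the threshold depended on the variance model, on the weight given to each array and on the scaling. With limma's trend and robust settings 173 probes passed, 149 higher and 24 lower, and with array weights 54 passed, 49 higher and 5 lower. With scaling on the spike-in probes 132 passed, 54 higher and 78 lower, so that the more frequent direction was the opposite one. Relative to the planned scaling, it moves all probes of an array together, by 2.80 (geniposide 2) to 3.33 (geniposide 3) log2 units. Groups did not overlap at 91 of the 132. The adjusted and unadjusted counts with it therefore also reflect this common shift, not only the spread of single probes. With the slide row as a fixed block 1 probe passed. Row 2 held no untreated array, so that fit compares geniposide 1 alone with the untreated arrays.

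Among the probes with the smallest p, none of which passed, RATLNCRNA_34539 (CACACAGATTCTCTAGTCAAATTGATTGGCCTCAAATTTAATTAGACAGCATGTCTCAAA) was measured at -2.36 ± 0.0766 (SD, n = 3) in geniposide and -3.23 ± 0.0334 (SD, n = 3) in untreated cells, relative to the 75th percentile. The log2 difference was 0.87 (SE 0.060, limma adjusted p = 0.0878), or 1.83-fold. It passed when the test was limited to probes well above background on all 6 arrays (adjusted p = 0.0458). Over the alternatives its log2 difference ran from 0.46, with normexp, to 0.93, and its adjusted p from 0.00949 to 0.344. RATLNCRNA_39274 (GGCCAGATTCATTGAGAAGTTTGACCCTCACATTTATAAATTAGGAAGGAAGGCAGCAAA) had a log2 difference of 0.93 (SE 0.082, limma adjusted p = 0.1), or 1.91-fold, with group values of -1.13 ± 0.141 (SD, n = 3) and -2.06 ± 0.0491 (SD, n = 3). Its log2 difference ran from 0.64, with normexp, to 1.01 over the alternatives, and its adjusted p from 0.00479 to 0.344. In the other direction, RATLNCRNA_9437 (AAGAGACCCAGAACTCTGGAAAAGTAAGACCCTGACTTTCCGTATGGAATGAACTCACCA) was well above background on 3 untreated arrays and on 0 geniposide arrays. The bound put it at least 1.20-fold lower in geniposide cells, with no error given, and it did not pass (limma adjusted p = 0.1). On untreated 2 and 3 it lay at -5.08 and -4.98, below a detection limit common to all arrays (-4.78). Its log2 difference ran from -2.38 to -0.26 over the alternatives, the smallest in size with normexp. Over the alternatives its adjusted p ran from 2.25e-20, with scaling on the spike-in probes, to 0.515, with normexp. That spike-in scaling was chosen after seeing the data and moves all probes of an array together. A p as small as 2.25e-20 rests on the spread that limma shares across probes, not on 1 probe's values on 6 arrays. The p-values from this scaling are therefore not read as evidence for single probes. RATLNCRNA_17301 (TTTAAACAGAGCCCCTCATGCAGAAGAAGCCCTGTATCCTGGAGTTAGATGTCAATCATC) had a log2 difference of -0.93 (SE 0.114, limma adjusted p = 0.1). Its group values were -5.16 ± 0.206 (SD, n = 3), well above background on 1 of 3 geniposide arrays, and -4.22 ± 0.102 (SD, n = 3), well above background on all 3 untreated arrays. Over the alternatives its log2 difference ran from -1.05 to -0.16, the smallest in size with normexp. Its adjusted p ran from 0.000651, again with scaling on the spike-in probes, to 0.71. The other 8 probes chosen by the same rule had adjusted p from 0.1 to 0.122. At each of the 12 probes the 3 geniposide arrays lay on 1 side of the 3 untreated arrays. Picking probes by the smallest p on these same arrays favours this, so it adds no support.

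**Figure D2:**
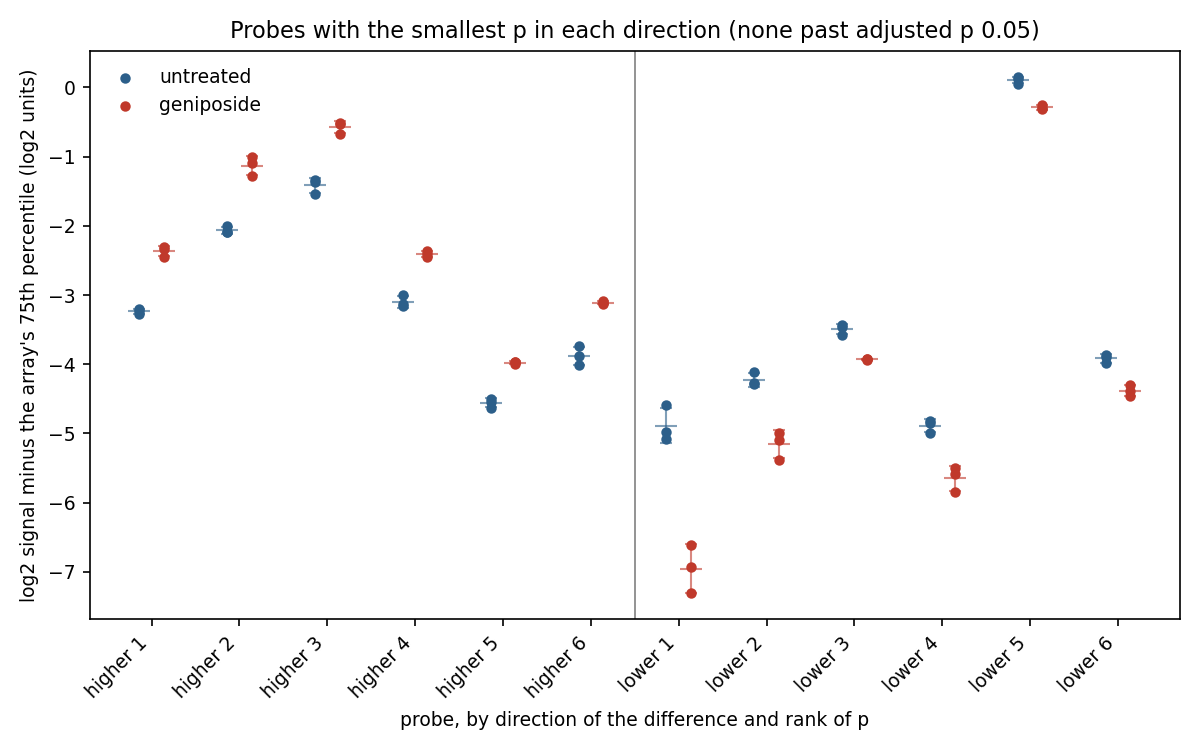
Log2 signal minus the array's 75th percentile (vertical axis) for the 6 probes with the smallest p in each direction (horizontal axis, ranked by p). Points are single arrays and bars are the mean and SD of 3 arrays. Groups do not overlap at any of the 12 probes, which picking them by p on the same arrays favours. The smallest adjusted p (limma) is 0.0878.

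The direction of the differences changed with brightness. Among the 9749 dimmest probes, with a median processed intensity of 31.6, there were 1205 higher and 541 lower at an unadjusted p under 0.05, so that 69.0% were higher. Among the 9748 probes of middle brightness 772 were higher and 418 lower. Among the 9749 brightest probes, with a median intensity of 2130, 166 were higher and 517 lower, so that 24.3% were higher. Chance would give 244 each way in each class. This split depended on the kind of scaling. With quantile normalization 44.6% of the dimmest and 55.4% of the brightest calls were higher. In the authors' deposited values, which lay close to quantile-normalized signal, the shares were 43.9% and 52.7%, and with cyclic loess 57% and 55.6%. The dimmest class kept the larger share with normexp (87.7% against 22.6%), median scaling (65.3% against 14.7%) and scaling on the spike-in probes (37.1% against 1.82%). It also did so with the percentile over probes well above background on all arrays. Over all probes, 59.2% of the unadjusted calls were higher, against 49.2% with quantile normalization, 47.9% in the deposited table and 35.8% with scaling on the spike-in probes.

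**Figure D3:**
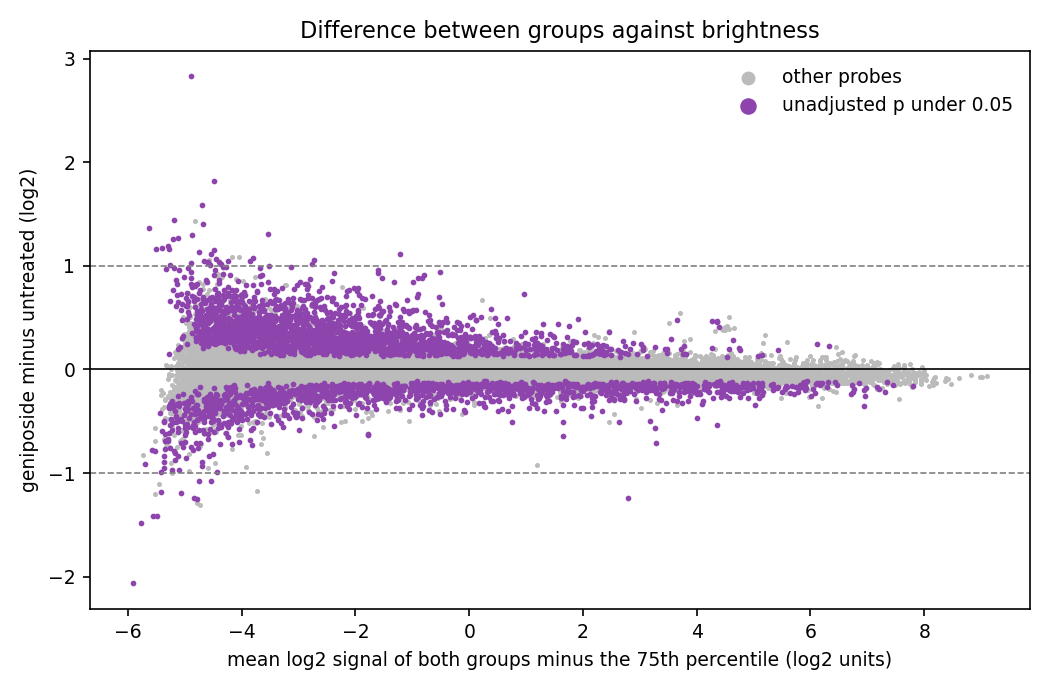
Log2 difference of geniposide minus untreated arrays (vertical axis) against the mean log2 signal relative to the 75th percentile (horizontal axis) for 29246 probes. Purple points are the 3619 probes with an unadjusted p under 0.05, dashed lines mark 2-fold, and the purple points lie mainly above 0 at low brightness and mainly below 0 at high brightness.

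Of the analysed probes, 27478 were well above background on all 6 arrays and 13207 on no array. A further 8 probes were well above background on all 3 geniposide arrays and 0 untreated arrays, and 98 on all 3 untreated arrays and 0 geniposide arrays. These counts depended on the detection limit of each array, which was higher on geniposide 2 and 3. They were the only arrays of row 2, so the row and the treatment cannot be told apart here. With 1 common limit for all arrays the direction turned, with 42 probes above it in geniposide arrays alone and 27 in untreated arrays alone. The smallest adjusted p (limma) was 0.124 among the 8 and 0.1 among the 98, so none passed.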

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

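Scaling on spike-in probes, cyclic loess, the trend setting alone, the first slide row alone and keeping outlier-marked spots were chosen after seeing the data. The count of 0 probes changed held with quantile normalization, median scaling, the percentile over probes well above background on all arrays, the deposited table, no filter, the random row block, the replicate block, adjusted p with 2-fold, cyclic loess and marked spots kept. With trend and robust settings 173 probes passed (149 higher, 24 lower, 173 with no overlap between groups), and with trend alone 121 (107 higher, 14 lower, 121 with no overlap). With array weights, which gave geniposide 3 a weight of 0.293, 54 passed (49 higher, 5 lower, 54 with no overlap). A 2-fold difference with an unadjusted p under 0.05 gave 44 (33 higher, 11 lower). Scaling on spike-in probes shifted the median difference by -0.13 log2 and gave 132 (54 higher, 78 lower, 91 with no overlap). Normexp gave 3 (3 higher, 3 with no overlap) and the stricter filter 1 (1 higher, 1 with no overlap). Of these 4 calls, 3 were among the 12 described probes and the other was RATLNCRNA_7313. The fixed row block gave 1 higher and row 1 alone 1 higher (1 with no overlap), RATLNCRNA_9357, with an adjusted p of 0.645 in the planned fit. Both compare geniposide 1 alone with the untreated arrays, so they are 1 result, and the lone array is assumed to vary like the others. The trend settings left each log2 difference as in the planned fit, so their calls come from the variance model alone. The causes of the other differences were not tested.

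Leaving out 1 array at a time gave 0 to 1 probes changed, 0 to 1 higher, 0 to 1 lower and 0 to 1 with no overlap. The calls were RATLNCRNA_27564 without geniposide 1 and RATLNCRNA_1734 without geniposide 3, singled out, like RATLNCRNA_9357 and RATLNCRNA_7313, after the values were seen. Unadjusted calls fell from 3619 to 2370 without untreated 3, to 2158 with normexp and to 1129 with scaling on spike-in probes, where chance gives 1462. The lowest correlation between 2 arrays, 0.994, became 0.997 with normexp, 0.989 with no filter and 0.997 in row 1 alone, and ran from 0.994 to 0.997 with 1 array left out, highest without geniposide 3. The replicate block left 0 calls (3091 unadjusted). Deviations of same-numbered arrays correlated at -0.0039, 0.018 and -0.097, and those of differently numbered arrays at -0.071 to 0.078. No deviation shared by same-numbered arrays was seen, which cannot tell whether the samples were handled in pairs. Over the alternatives the 12 described probes, picked by p on the same arrays, gave 273 values, of which 273 had the sign of the planned fit and 31 passed. Some sizes shrank with normexp, for RATLNCRNA_34539 from 0.87 to 0.46 and for RATLNCRNA_17301 from -0.93 to -0.16. Counts of messenger and noncoding RNA probes, the gene lists, the mean of a gene's probes and the estimated correlation of the set test were not run, since probes had no gene names. Dim probes limit the precision: the median SE was 0.117 log2 among the dimmest and 0.0636 among the brightest.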

Other observations

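The tests of the splits, of the slide row, and of brightness and GC content for the poly(A) classes were chosen after the results they concern had been seen. So were the intervals across arrays without geniposide 3, the common detection limit, the sequence groups and the probe pairs described here.

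Among 3765 bright probes, more than 3 log2 units above the 75th percentile, 19 had a log2 difference over 0.3 and 18 one under -0.3. The 19 fell mostly into a pair of sequence groups. A group of 3 overlapping probes shared 50 bases (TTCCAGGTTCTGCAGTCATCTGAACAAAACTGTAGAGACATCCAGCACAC). Their log2 differences ran from 0.46 to 0.47 (SE 0.057 to 0.075, limma adjusted p from 0.1 to 0.124), with median excesses over untreated arrays of 0.41, 0.38 and 0.57 on geniposide 1, 2 and 3. None of the 3 passed the threshold. A group of 13 shared 26 bases (GGCTGGAGAGATGGCTCAGCCGTTAA), a stretch found in 17 tested probes with a median processed intensity of 8470. Their median log2 difference was 0.39, with adjusted p from 0.529 to 0.839. The excess over untreated arrays was 1.20 on geniposide 3, against 0.07 on geniposide 1 and -0.09 on geniposide 2, so it rested on 1 array.

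Overlapping probes moved together. In 2046 pairs that shared at least 25 bases on the same strand, the log2 differences correlated with a Spearman's rho of 0.662, across probe pairs that are not independent replicates. It was 0.0194 when the partner was replaced by a probe of like brightness. In 126 pairs on opposite strands of 1 sequence, the levels correlated with an r of -0.02 and the log2 differences with a rho of 0.238. Replaced partners of like brightness gave -0.19. They were drawn at random once, so over 126 pairs this value is not a firm baseline for 0.238.

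The 6 arrays can be split into 3 and 3 in 10 ways. The real split gave 0 probes past the adjusted threshold, as did the highest of the others, and with a real count of 0 the comparison of splits tests nothing. At an unadjusted p under 0.05 the real split gave 3619 probes and the highest of the others 1334. With trend and robust settings the real split gave 173 and the highest of the others 0. A set of 10 splits is too few for a share under 0.05.

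The excess of higher calls among dim probes was the first pattern examined, at 69.0% of the unadjusted calls in the dimmest class. Leaving out geniposide 3 left 65.5%, and the median deviation of dim minus bright probes was still 0.0568 log2 units higher in geniposide 1 and 2 than in untreated arrays (95% interval across arrays 0.00878 to 0.105), which argues against that array as the whole cause. After cyclic loess over brightness the share was 57.0%, and with quantile normalization it was 44.6%. Both methods remove a trend with brightness whatever its source, so these values do not tell a difference in scaling from a biological one. Within row 1, geniposide 1 against the untreated arrays gave 59.9%, but 1 array cannot tell the slide row from the treatment. The background level differed between arrays too. Negative control spots had a processed intensity of 1.98, 2.78 and 2.75 on geniposide 1, 2 and 3, and 1.59, 2.03 and 2.19 on untreated 1, 2 and 3. An effect of geniposide stays open and was not tested apart from the slide's row or column or from the background level.

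The second pattern was the 98 probes detected in untreated arrays alone, against 8 in geniposide arrays alone. The lowest signal well above background was 11.9 and 11.9 on geniposide 2 and 3 in row 2, and 8.76, 7.10, 8.70 and 9.64 on the arrays of row 1. A further 406 probes were detected on all 4 arrays of row 1 and neither of row 2, 4.14 times the 98. A higher detection limit on geniposide 2 and 3 is therefore a possible source of the excess. Row 2 held no untreated array, so the row cannot be told from the treatment. With 1 common limit for all arrays the counts became 27 in untreated and 42 in geniposide arrays alone. The median log2 difference of the 98 was -0.42 (95% interval across probes, not arrays, -0.556 to -0.365). These probes lay near the detection limit and were chosen for detection in untreated arrays alone, which favours a negative value. The median therefore cannot tell whether the RNA level was lower in treated cells.

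The third pattern was a difference between probes with and without a poly(A) signal hexamer (AATAAA or ATTAAA) in their sequence. The median log2 difference was 0.00 for 22571 probes without it and -0.04 for 6675 with it, and 8.33% against 3.93% were higher at an unadjusted p under 0.05. Of this difference of 0.04 log2 units, 61.4% stayed after matching on brightness (bootstrap over probes, 95% interval 53.3 to 67.4) and 96.5% after matching on GC content (92.6 to 101), which argues against each as the whole cause in these 6 arrays. Those intervals take probes as independent, although some overlap in sequence, and leave out the spread between arrays. As a deviation from the mean of the 6 arrays, the class difference was -0.00303, 0.0195 and 0.0486 on geniposide 1, 2 and 3 and -0.0102, -0.0279 and -0.0205 on untreated 1, 2 and 3. Without geniposide 3, 67.6% stayed, but the 95% interval across arrays ran from -0.00633 to 0.0619 log2 units, so that array as the source stays open. The unmatched difference of 0.0403 depended on the scaling, at 0.0142 with quantile normalization, 0.0147 in the deposited values and 0.0208 with cyclic loess. The brightness-matched difference of 0.0247 moved less under these 3, at 0.0232, 0.0227 and 0.0245 in the same order. With normexp it moved more than the unmatched one, to 0.0169 matched and 0.0351 unmatched. In row 1, where geniposide 1 was the single treated array, the unmatched difference was 0.0159 and the matched one 0.00735, so the treatment and the position on the slide both stay open.

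Spots more than 4-fold above the same spot on the other arrays lay in different parts of the arrays by slide row. In row 2, 95.9% of 98 such spots on geniposide 2 and 96.0% of 75 on geniposide 3 lay in the first 50% of the array's rows. In row 1 it was 12.2% of 41 on geniposide 1, and 7.41% of 27, 0% of 55 and 9.38% of 32 on untreated 1, 2 and 3. Where the probe had a second spot, that spot exceeded the other arrays by 2-fold in 1 of 17 cases on geniposide 1, 1 of 49 on geniposide 2 and 4 of 45 on geniposide 3, and in 0 of 12, 3 of 32 and 0 of 16 on untreated 1, 2 and 3. The median excess of the second spot was 0.529 log2 units on geniposide 3 and 0.243 on geniposide 2, against -0.172 on geniposide 1 and -0.196, -0.145 and -0.156 on untreated 1, 2 and 3. Negative control spots, relative to the 75th percentile, also lay highest on geniposide 3 (-6.895) and geniposide 2 (-7.266). They lay at -7.655 on geniposide 1 and at -7.749, -7.645 and -7.524 on untreated 1, 2 and 3. The medians therefore do not show that second spots repeated the excess rather than a higher background, and the cause was not tested.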
